A study of Homo sapiens with 6 samples.

How the data were processed

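RNA was measured in 6 libraries from WA01 human embryonic stem cells and their derivatives, 2 labelled replicates each of undifferentiated cells (day 0, ES), pre-neural crest cells (day 3, preNC) and neural crest cells (day 5, NC). Per the labels' protocols, cells were plated at 20000 per cm2 on Matrigel in medium with 2% B27 supplement, 0.5% bovine serum albumin and 3 µM CHIR99021, with 10 µM of the ROCK inhibitor Y-27632 over the opening days. Total RNA was extracted with TRIzol, and libraries were made from poly-adenylated RNA with a custom kit based on Illumina mRNA-seq. Nothing in the labels says whether replicates came from separate cultures, so the authors' p-values may measure only technical spread between samples.

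The submitters' processing notes name TopHat2 2.0.10, TopHat without a version, Cuffdiff 2.1.1 and the genome build hg19. The annotation used, the read length and strandedness are not given in the sources used here. A single table was used, in the format Cuffdiff writes for gene-level tests, with 69852 rows for 23284 genes in 3 comparisons. Per the file headers it gives, for each gene and comparison, a test status and the authors' FPKM value of each group, with the libraries of a group combined. It also gives the test statistic of Cuffdiff, used here as a score, and the deposited p-value and q-value. Since no value per library was used, no replicate-level test, standard deviation or sample check could be made here, and the depth of each library is unknown. The lowest FPKM values were looked at for steps of 1 fragment. Of the 1000 lowest values above 0, 982 on day 0, 980 on day 3 and 992 on day 5 were distinct, so no step could be read. Of the FPKM sum, 27.0% on day 0, 25.9% on day 3 and 21.9% on day 5 lay in the small RNA genes MIR4461, MIR1244-1 and MIR1244-3.

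Several properties of the deposited table were checked before use. The q values equal the Benjamini-Hochberg adjustment of the deposited p over the 48572 tested rows of all 3 comparisons, to within 5.25e-07. The smallest p is 5e-05, shared by 4078 tested rows, so genes cannot be ranked by p beyond it. The largest p among called rows in the authors' deposited table was 0.0101, and the test statistic near that border had a median size of 1.90, which a normal distribution would reach more often than that p. The fold change column held spreadsheet error text in 1796 cells, and 38 of 48251 finite tested rows, 5 of them called, differed from the ratio of the FPKM values by over 0.001. That column was therefore not used, and folds were computed from FPKM. The test statistic held error text in 321 cells, where a group is listed at 0. The symbols of 28 genes had been turned into dates by a spreadsheet, so the gene identifier column was used instead. Another 91 genes carry merged symbols, 238 lie on haplotype contigs of the build (POU5F1 among them) and 5977 share their locus with another gene. KRT8 and KRT18 are listed at 0 with a failed estimate. Locus widths matched reference gene lengths as end minus start for 1901 genes and as end minus start plus 1 for 253. Start positions were therefore taken as counted from 0 and are printed counted from 1. Gene lengths came from the RefSeq table of GRCh38.p14, in which 19793 identifiers were found by symbol, and no coordinates of that build were used.

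A gene was tested where its status was OK and called where its deposited q was below 0.05, with the direction from the FPKM values. The log2 fold change divided by the deposited test statistic gave the implied standard error. That error did not always match the deposited q. Between day 0 and day 3 it was 0.00562 for MIR363 (log2 2.75) at a deposited q of 0.505. Between day 0 and day 5 it was 44.5 for SNORA68 (log2 2.29) at a deposited q of 0.0868. The implied errors are therefore descriptions, and the simulations that take them as normal share this limit. Gene lists were compared on log2 of FPKM plus a pseudocount of 1, which understates changes of weakly expressed genes. For each of 30 lists, of which the HOX and FOX families were taken by symbol, members called higher and lower were counted. The deposited p was then adjusted by Benjamini-Hochberg over the tested members ("adjusted over the list alone"). The list's median was placed among the medians of 10000 random lists drawn from 10 bins of mean expression, as a description of these groups and not as a test. FOXB1 formed a list of its own. Of 528 listed symbols 1 was absent from the table. The genes named were fixed by rule before the data were examined. FOXB1 came first. For each comparison, the 12 largest rises and 12 largest falls on that log2 scale were taken among called genes with an FPKM of at least 5 in the higher group. Symbols starting LOC, LINC, MIR, SNOR, SCARNA or RNU, merged symbols, XIST and Y-linked genes were left out. From each list, up to 4 members with the largest change and an FPKM of at least 1 in either group were taken, plus members needed to make a count clear. SOX2, LIN28A, CDH2, VIM, SOX9, SOX10 and MKI67 are list members that this rule does not name and were chosen after their values were seen. Some genes that the rule names are not reported here. Genes leading the trajectory classes were ranked by the smaller of their steps, a ranking chosen after the values were seen.

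The step from day 0 to day 3 and the step from day 3 to day 5 share the preNC libraries. Variances per group were solved from the implied standard errors of the 3 comparisons, and 100 simulated sets of unchanged genes were called at a statistic of 1.90. The calculations were tested on simulated data built from 16123 genes of the preNC versus ES comparison with 200 changed genes. With normal errors of the implied size, 8% of the genes changed 2-fold and 65.5% of those changed 4-fold were called, with 0 and 3 unchanged genes called. Calls there used a normal p with Benjamini-Hochberg adjustment, so these rates do not describe calls by the deposited q. All 10 planted lists lay outside the central 95% of random lists at each fold, as did 4 and 6 of 100 lists of unchanged genes.

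Alternatives set before the data were examined were a q threshold of 0.01, a minimum absolute log2 fold change of 1, a minimum FPKM of 1, adjustment within each comparison, recentring on the median, leaving out merged symbols, pseudocounts of 0.1 and 5 or none, unmatched random lists and list means. Added after seeing the data were leaving out small RNA genes, leaving out genes that share a locus, and a two-sided normal p of the deposited test statistic. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.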

Results

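Poly-adenylated RNA was sequenced during the induction of neural crest, the migratory cell population of the vertebrate embryo that gives rise to peripheral neurons, glia, pigment cells and parts of the face, from human embryonic stem cells. The cells were WA01 (also called H1), an established embryonic stem cell line, with a wildtype genotype. For induction, the labels' protocols say that cells were dissociated, plated at 20000 cells per cm2 and cultured with 3 µM CHIR99021. CHIR99021 is an inhibitor of the kinase GSK3 that activates WNT/beta-catenin signalling. These settings are listed for every library, also those of undifferentiated cells on day 0, so they do not show which cells were treated. The 6 libraries fall into 3 groups of 2, namely undifferentiated cells on day 0 (ES), pre-neural crest cells on day 3 (preNC) and neural crest cells on day 5 (NC). The deposited table gives 1 FPKM value (fragments scaled to transcript length and library size) per gene and group for 23284 genes, so no spread between replicates could be computed. The number of fragments per library is unknown. Genes at an FPKM of at least 1 numbered 13428 on day 0, 13250 on day 3 and 13296 on day 5. Fold changes below are log2 ratios of the group FPKM values, and the number after ± is the standard error implied by the test statistic in the authors' deposited table. A gene is called higher or lower where the q in that table is below 0.05. For some genes the implied standard error and that q disagree widely. Rises and falls are called largest on the log2 ratio of FPKM plus 1, among called genes at an FPKM of at least 5 in the higher group. Gene positions refer to hg19.

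The design asks how the transcriptome changes as embryonic stem cells pass to pre-neural crest and on to neural crest, and the series title names the forkhead transcription factor FOXB1. FOXB1 (chromosome 15, 60296421 to 60298142) was at an FPKM of 3.77 on day 0, 73.6 on day 3 and 4.08 on day 5. It rose 19.5-fold between day 0 and day 3 (log2 4.29 ± 0.26) and fell by 4.17 ± 0.29 on the log2 scale between day 3 and day 5. Both steps had a q of 0.000596 in the authors' deposited table. Day 5 did not differ detectably from day 0 (log2 0.11 ± 0.34, with a q of 0.913 in the authors' deposited table).

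**Figure D1:**
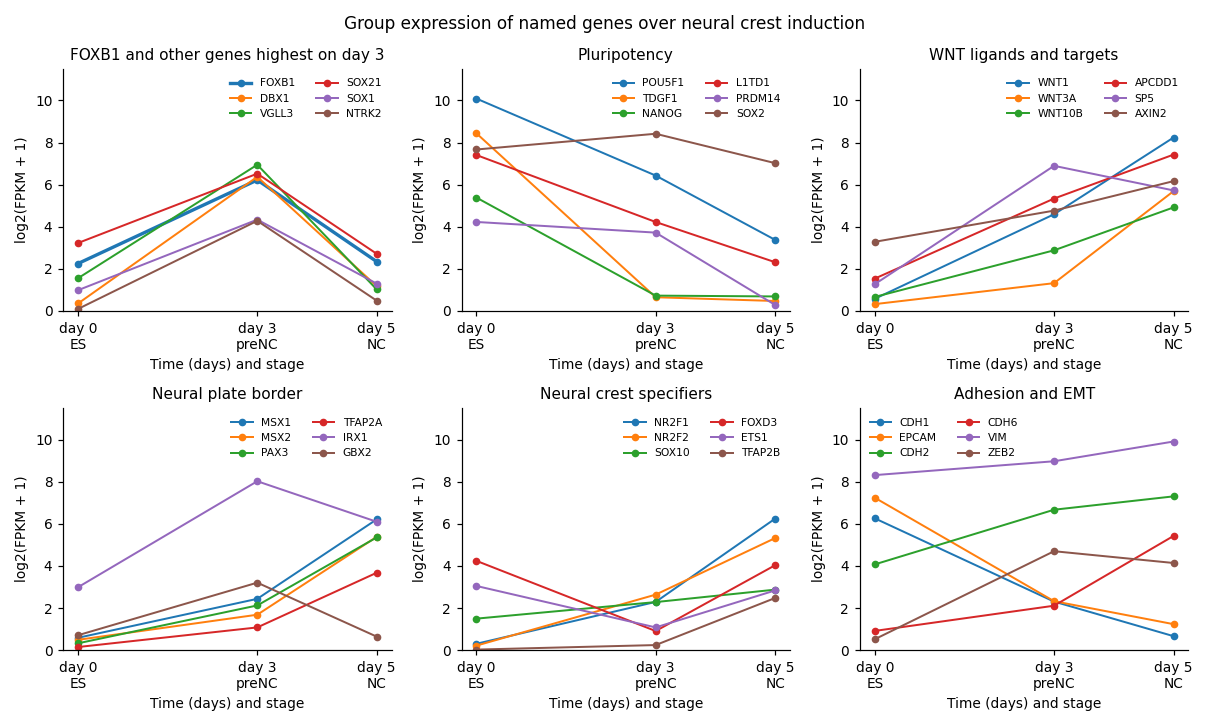
Group expression as log2(FPKM + 1) on the vertical axis against day 0 (ES), day 3 (preNC) and day 5 (NC) for 6 genes in each of 6 panels. Each point is the authors' value for a group, so no error bars are drawn. FOXB1 goes from 3.77 to 73.6 and back to 4.08 FPKM, while POU5F1 falls from 1087 to 9.40 and WNT1 rises from 0.496 to 301.

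Between day 0 and day 3, most tested pluripotency genes fell, and most tested WNT feedback targets, neural plate border genes and neural progenitor genes rose. The largest rise was that of DBX1, a homeobox gene of neural tube progenitors, from 0.282 to 81.9 (log2 8.18 ± 0.46). It was followed by SP5, a transcription factor induced by WNT signalling (1.42 to 118, log2 6.38 ± 0.33), the Notch ligand-like gene DLK1 (6.79 to 359), the TEAD cofactor VGLL3 (1.95 to 122) and the homeobox gene DMBX1 (0.331 to 45.3). The Iroquois gene IRX1 rose from 6.95 to 259, MEIS2 from 0.211 to 37.2, and CYP26C1, which degrades retinoic acid, from 1.74 to 77.5. CNTFR, WLS (the carrier of WNT proteins to the cell surface), PRTG and CNTN2 completed the 12 largest rises, with day 3 values of 56.9, 74.0, 83.4 and 38.9. The largest fall was that of TDGF1, a Nodal co-receptor, from 345 to 0.573 (log2 -9.24 ± 0.62). ADM fell from 138 to 1.21, the metallothioneins MT1H and MT1G from 183 to 2.79 and from 391 to 11.7, EPCAM from 149.9 to 4.01 and RAB17 from 31.3 to 0.0779. FOS fell from 44.1 to 0.748, PMAIP1, a pro-apoptotic BH3-only gene, from 82.6 to 2.28, and NANOG from 40.8 to 0.659. TDGF1P3 (34.9 to 0.0937) is a pseudogene of TDGF1 and TPTEP1 (88.1 to 2.35) a transcribed pseudogene, so their values are uncertain. SNAR-C3, a very short gene (chromosome 19, 48453553 to 48453671), went from 29.9 to a listed value of 0 and stood at 7.96 on day 5. It has no usable test statistic and was not called under the normal p, and its FPKM can rest on few fragments.

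Of 20 pluripotency genes tested, 13 fell by day 3 and none rose (13 and 1 adjusted over the list alone). POU5F1, the core pluripotency factor, fell from 1087 to 85.3 (log2 -3.67 ± 0.43), and L1TD1 from 169 to 17.7. SOX2 (203 to 341) and LIN28A (396 to 555) were not called. The list's median log2 ratio of FPKM plus 1 was -1.87, below every one of 10000 random lists matched on expression. Of 8 tested Nodal pathway genes 5 fell and none rose (6 and 1 adjusted over the list alone), among them LEFTY1 (4.34 to 0.147) and FOXH1 (60.2 to 17.4). WNT feedback targets rose in 12 of 14 tested members and fell in 0 (12 and 0 adjusted over the list alone), with APCDD1 going from 1.91 to 39.5, TNFRSF19 from 0.889 to 24.9 and LEF1 from 0.914 to 14.4. WNT ligands rose in 8 of 12 tested members (11 adjusted over the list alone), WNT1 from 0.496 to 23.1 and WNT4 from 0.862 to 13.2. FGF pathway genes fell in 8 and rose in 3 of 15 tested members (also 8 and 3 adjusted over the list alone). The feedback genes DUSP6 (61.2 to 3.52) and SPRY4 (23.9 to 1.87) and the transcription factors ETV4 (50.3 to 3.56) and ETV5 (6.39 to 0.480) were among those that fell.

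Neural plate border genes rose in 15 of 18 tested members by day 3 and fell in 0 (16 and 1 adjusted over the list alone). Besides IRX1, IRX5 rose from 0.870 to 17.0, IRX3 from 1.64 to 16.4 and GBX2 from 0.635 to 8.22. Neural progenitor genes rose in 10 and fell in 2 of 15 tested members (11 and 2 adjusted over the list alone), with LIX1 going from 1.12 to 35.1, SOX1 from 0.985 to 19.2 and SOX21 from 8.38 to 91.0. Midbrain and hindbrain genes rose in 8 and fell in 2 of 11 (9 and 2 adjusted over the list alone), PAX2 from 0.0383 to 11.03 and EN1 from 0.0341 to 7.55. Neural crest specifiers went both ways, with 8 higher and 5 lower of 20 tested (9 and 5 adjusted over the list alone). NR2F2 rose from 0.161 to 5.22, SOX5 from 0.289 to 5.09 and CXCR4 from 1.94 to 12.5, whereas FOXD3 fell from 17.9 to 0.876 (log2 -4.35 ± 0.35). BMP pathway genes rose in 8 and fell in 3 of 16 (8 and 3 adjusted over the list alone). The antagonist FST rose from 11.01 to 183 and BMP5 from 0.0879 to 6.57, and ID1 fell from 119 to 11.3. Notch pathway genes rose in 6 and fell in 1 of 15 (7 and 2 adjusted over the list alone), with DLL1 going from 1.96 to 12.1, JAG1 from 8.96 to 35.7 and HEY2 falling from 3.99 to 0.313.

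Adhesion and EMT genes, EMT being the transition from epithelial to mesenchymal cells, rose in 9 and fell in 5 of 21 tested members (10 and 8 adjusted over the list alone). The epithelial splicing factor ESRP1 fell from 50.1 to 1.28 and the cadherin CDH1 from 75.6 to 3.95, while the cadherin CDH2 rose from 15.8 to 101 and ZEB2 from 0.434 to 24.97. CLDN7 went from 71.8 to 1.36 (log2 -5.72 ± 1.62) without a call. Its deposited test statistic was -3.54 and its deposited q 0.0634, and the cause of the missing call was not tested. Neurogenesis genes rose in 8 and fell in 3 of 20 (10 and 3 adjusted over the list alone), with NTRK2, the receptor of BDNF, going from 0.0714 to 18.5 and STMN2 from 2.60 to 27.4. Of 18 stress genes 6 fell and none rose (8 and 1 adjusted over the list alone), EGR1 from 63.0 to 5.12 and IER2 from 93.5 to 29.5. Glycolysis genes fell in 3 of 18 (3 adjusted over the list alone), namely HK1 (89.8 to 22.5), PFKP (72.2 to 30.4) and ALDOC (76.2 to 29.3). Chromatin genes rose in 5 and fell in 3 of 14 (6 and 3 adjusted over the list alone), with PHC1 falling from 184 to 21.2 and JARID2 from 67.8 to 26.2. Anterior neural genes counted 4 higher and 4 lower of 10 (4 and 5 adjusted over the list alone), OTX1 going from 1.25 to 17.8. Neural crest derivative genes counted 5 higher and 2 lower of 17 (6 and 3 adjusted over the list alone), COL2A1 rising from 4.89 to 34.6. Nonneural ectoderm and placode genes counted 4 higher and 3 lower of 11 (4 and 4 adjusted over the list alone). Their median was 0.10 and their mean -0.0379.

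Among the remaining lists, cell cycle inhibitors and p53 targets counted 2 higher and 1 lower of 13 by day 3 (4 and 1 adjusted over the list alone). No proliferation gene of 20 was called (0 adjusted over the list alone). Cholesterol synthesis genes counted 1 lower of 17 (0 adjusted over the list alone), and housekeeping genes 1 higher and 1 lower of 15 (1 and 1 adjusted over the list alone). Only 1 HOX gene, HOXA2, was tested, at 1.97 on day 3 without a call (0 adjusted over the list alone). Mesendoderm genes counted 1 higher and 2 lower of 9 (3 and 5 adjusted over the list alone) and endothelial genes 2 higher and 2 lower of 6 (2 and 4 adjusted over the list alone). Muscle genes counted 3 lower of 5, hepatic and gut endoderm genes 2 lower of 4, and trophoblast and amnion genes 1 higher and 3 lower of 5, with the same counts adjusted over the list alone.

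In all, 1454 genes were higher and 1884 lower on day 3 than on day 0, of 16231 tested, at a q below 0.05 in the authors' deposited table. The median log2 ratio of all genes at an FPKM of at least 1 in both groups was 0.05. With a stricter q threshold of 0.01 the number of higher genes was 946. Recomputing p from the deposited test statistic under a normal distribution gave 915 higher genes.

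**Figure D2:**
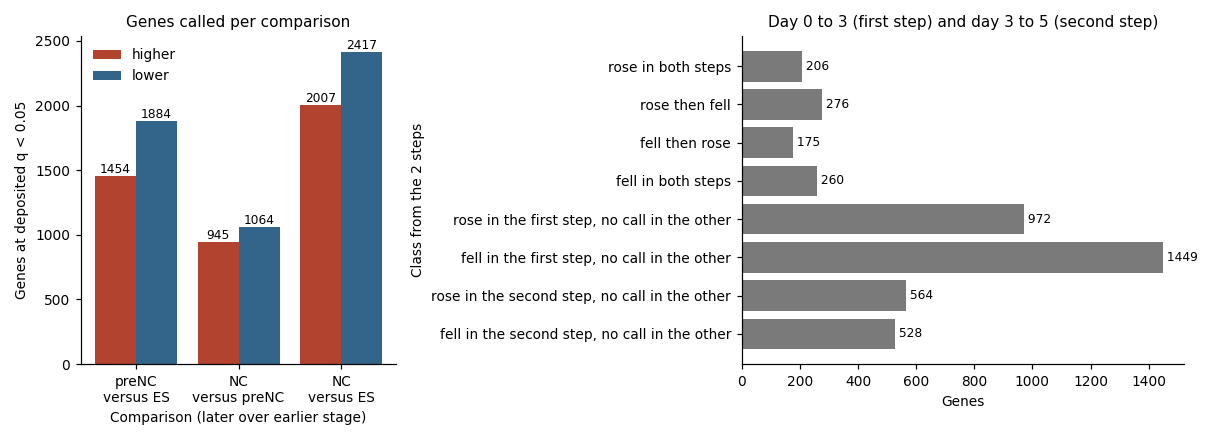
Left, number of genes called higher (red) and lower (blue) in each comparison at a q below 0.05 in the authors' deposited table. Right, number of genes in each combination of calls in the step from day 0 to day 3 and the step from day 3 to day 5, where 276 genes rose and then fell and 175 fell and then rose.

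Between day 3 and day 5, 9 of 15 tested BMP pathway genes and 7 of 14 tested WNT ligands rose, neural plate border genes went both ways, and several genes that had been high on day 3 fell. The largest rise was that of WNT3A, from 1.5001 to 50.6 (log2 5.08 ± 0.41), followed by the homeobox gene LMX1A (1.91 to 46.8), the nuclear receptor NR2F1 (3.89 to 74.8) and ZFHX4 (1.88 to 41.9). ID1, a target of BMP signalling, rose from 11.3 to 174, the homeobox genes MSX1 and MSX2 from 4.41 to 73.2 and from 2.21 to 40.8, and WNT1 from 23.1 to 301. ANXA1, TFPI and the BMP antagonist NOG reached 99.8, 39.2 and 25.7. The largest fall was that of the bHLH repressor HES3, from 235 to 1.95 (log2 -6.91 ± 0.32). VGLL3 fell from 122 to 1.03, DBX1 from 81.9 to 1.26, SOX21 from 91.0 to 5.57 and NTRK2 from 18.5 to 0.404. The retinoic acid-degrading enzymes CYP26A1 and CYP26C1 fell from 59.9 to 3.65 and from 77.5 to 5.34. PIPOX, PRDM14, the noncoding RNA ESRG and GRB14 fell to 1.51, 0.221, 10.96 and 3.75, and FOXB1 had the fifth largest fall.

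Of the BMP pathway genes 9 rose and 1 fell of 15 tested (10 and 1 adjusted over the list alone), with the ligands BMP4 going from 1.69 to 27.5 and BMP2 from 3.27 to 41.4, and the antagonist GREM1 from 2.51 to 25.4. The listed genes include ligands, inhibitors and targets, so their rise gives no single direction of signalling. Their median log2 ratio of FPKM plus 1 was 1.51, above every random list. WNT ligands rose in 7 and fell in 2 of 14 (9 and 2 adjusted over the list alone), WNT2B from 1.46 to 12.8, while WNT8A fell from 5.96 to 0.533. WNT feedback targets rose in 6 and fell in 2 of 16 (7 and 2 adjusted over the list alone), with AXIN2 going from 26.2 to 70.9, DKK1 from 3.37 to 31.3, and SP5 falling from 118 to 52.0. Neural plate border genes rose in 8 and fell in 5 of 19 (also 8 and 5 adjusted over the list alone). PAX3 rose from 3.36 to 39.9, TFAP2A from 1.11 to 11.8 and ZIC1 from 0.483 to 8.53. GBX2, IRX1, IRX2 and IRX5 were among those that fell, GBX2 to 0.560 and IRX1 to 67.5. Neural crest specifiers rose in 10 of 23 tested members and fell in 0 (10 and 1 adjusted over the list alone). FOXD3 rose from 0.876 to 15.4 (log2 4.13 ± 0.43), SOX9 from 4.48 to 18.1 and TFAP2B from 0.182 to 4.57. SOX10 stood at 3.87 on day 3 and 6.33 on day 5 without a call in this step.

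Pluripotency genes fell in 9 of 18 tested members and rose in 0 (10 and 0 adjusted over the list alone), POU5F1 from 85.3 to 9.40, ZSCAN10 from 20.8 to 2.53 and UTF1 from 7.86 to 0.375. Midbrain and hindbrain genes rose in 7 and fell in 1 of 12 (8 and 1 adjusted over the list alone), with OTX2 going from 97.9 to 182. Neural progenitor genes went both ways, with 3 higher and 4 lower of 16 (4 and 6 adjusted over the list alone). PAX6 rose from 1.86 to 15.3, whereas SOX1 fell from 19.2 to 1.46. Neurogenesis genes rose in 7 and fell in 5 of 25 (7 and 6 adjusted over the list alone), POU4F1, a sensory neuron factor, from 5.71 to 26.3, and RET falling from 8.79 to 0.469. The list's median was 0.10 and its mean -0.13, so its sign depends on the summary used. Neural crest derivative genes rose in 7 and fell in 1 of 16 (7 and 1 adjusted over the list alone), with ACTA2, smooth muscle actin, going from 34.1 to 266 and COL2A1 from 34.6 to 123. Adhesion and EMT genes rose in 7 and fell in 5 of 22 (9 and 5 adjusted over the list alone), CDH6 from 3.32 to 41.9, ZEB1 from 1.85 to 5.72 and VIM from 501 to 960.1, and CLDN6 falling from 309 to 48.4. Notch pathway genes rose in 5 and fell in 2 of 15 (5 and 3 adjusted over the list alone), HES4 from 8.97 to 45.0. FGF pathway genes rose in 2 and fell in 2 of 15 (3 and 2 adjusted over the list alone). DUSP6 rose again from 3.52 to 9.67 and ETV5 from 0.480 to 3.47, with FGF8 falling from 4.87 to 0.732. Stress genes rose in 4 and fell in 3 of 18 (4 and 3 adjusted over the list alone), EGR1 from 5.12 to 25.7 and FOS from 0.748 to 6.17. Of the Nodal pathway genes 1 fell, FOXH1 from 17.4 to 1.21 (1 adjusted over the list alone). Nonneural ectoderm and placode genes counted 5 higher and 1 lower of 13 (5 and 1 adjusted over the list alone), and anterior neural genes 3 higher and 3 lower of 10 (4 and 3 adjusted over the list alone). Of 4 tested HOX genes HOXB2 rose and HOXA2 fell, from 1.97 to 0.141 (1 and 1 adjusted over the list alone).

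Mesendoderm genes counted 3 higher and 1 lower of 11 in this step (3 and 2 adjusted over the list alone), and endothelial genes 2 lower of 4 (2 adjusted over the list alone). Muscle genes counted 1 higher of 6, hepatic and gut endoderm genes 1 higher and 1 lower of 4, and trophoblast and amnion genes 1 higher and 2 lower of 4, with the same counts adjusted over the list alone. Proliferation genes counted 2 lower of 20 (0 adjusted over the list alone), chromatin genes 2 higher of 14 (0 adjusted over the list alone), and cell cycle inhibitors and p53 targets 2 higher and 2 lower of 14 (2 and 2 adjusted over the list alone). No glycolysis, cholesterol synthesis or housekeeping gene was called, of 18, 17 and 15 (0 adjusted over each list alone).

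In this step 945 genes were higher and 1064 lower of 15932 tested, at a q below 0.05 in the authors' deposited table. The median log2 ratio of all genes at an FPKM of at least 1 in both groups was -0.06. With a q threshold of 0.01 there were 586 higher and 619 lower genes, and the normal p of the test statistic gave 530 higher genes.

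**Figure D3:**
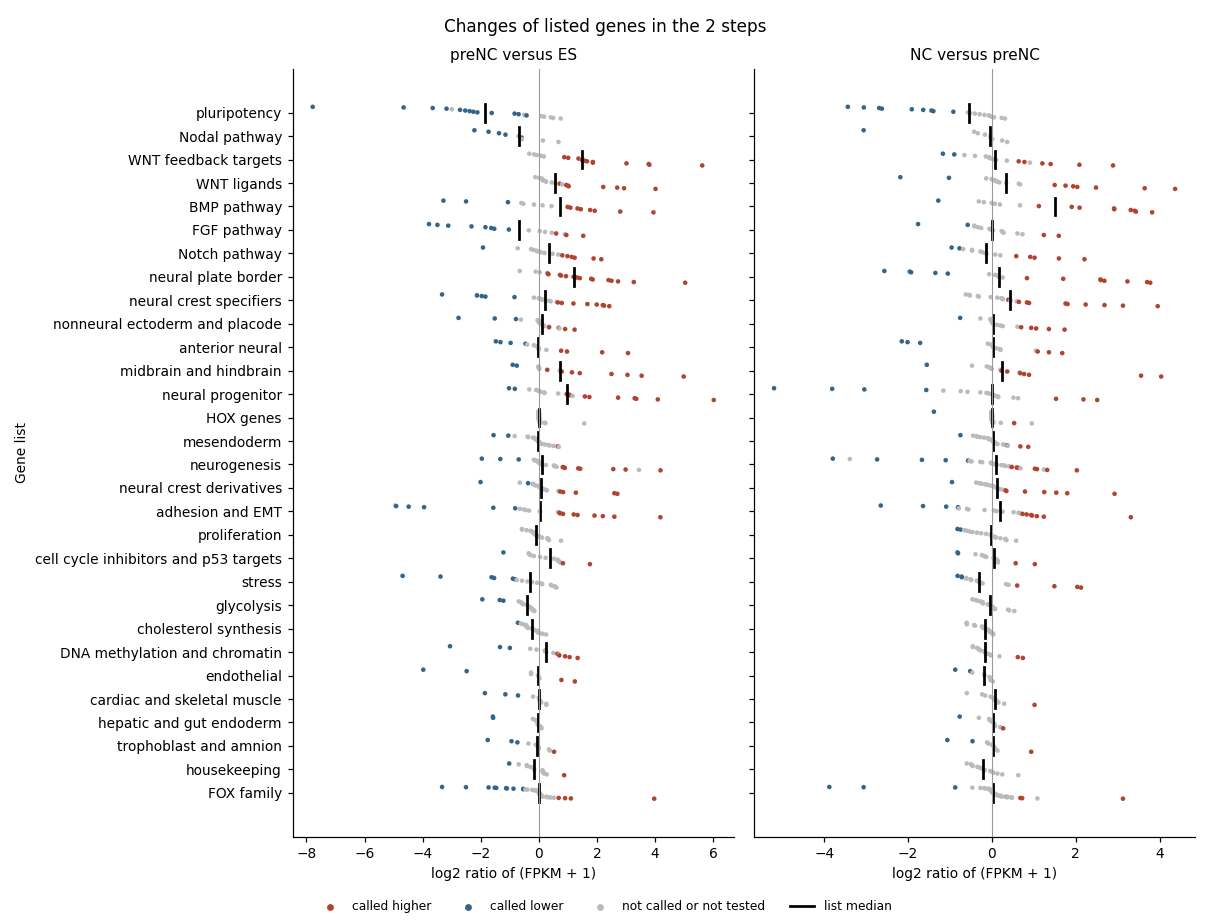
Log2 ratio of (FPKM + 1) of every measured member of 30 gene lists on the horizontal axis, for preNC versus ES (left) and NC versus preNC (right). Red points are members called higher, blue points members called lower, grey points members not called or not tested, and the black bar is the list's median, which is -1.87 for pluripotency genes on the left and 1.51 for BMP pathway genes on the right.

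Across the whole course, from day 0 to day 5, WNT1 had the largest rise, from 0.496 to 301 (log2 9.24 ± 0.42). WLS rose from 1.75 to 310.3, PRTG from 2.21 to 200.2, NR2F1 from 0.234 to 74.8, APCDD1 from 1.91 to 171 and MSX1 from 0.503 to 73.2. ACTA2, LMX1A, WNT3A, LGI1, CNTFR and NR2F2 ended at 266, 46.8, 50.6, 52.0, 74.9 and 39.0. TDGF1 had the largest fall, from 345 to 0.389 (log2 -9.79 ± 0.63), and POU5F1 fell from 1087 to 9.40 (log2 -6.85 ± 0.49). MT1H and MT1G ended at 0.922 and 4.58, the chemerin gene RARRES2 fell from 286 to 2.05, ESRG from 1031 to 10.96, the neuropeptide gene GAL from 186 to 1.84, EPCAM from 149.9 to 1.35, the epithelial adaptor gene AP1M2 from 82.2 to 0.619, ADM from 138 to 1.802 and CDH1 from 75.6 to 0.585. POU5F1P3 (239 to 1.62) shares most of its sequence with POU5F1, so the division of reads between them is uncertain.

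By day 5, pluripotency genes were lower in 15 and higher in 1 of 20 tested (18 and 1 adjusted over the list alone), the higher member being LIN28B (30.04 to 50.1). ZSCAN10 fell from 125 to 2.53 and L1TD1 from 169 to 3.98. Of 9 tested Nodal pathway genes 3 were lower and 1 higher (3 and 1 adjusted over the list alone). WNT feedback targets were higher in 13 of 16 and lower in 0 (13 and 1 adjusted over the list alone), and WNT ligands higher in 11 of 14 and lower in 0 (11 and 0 adjusted over the list alone). BMP pathway genes were higher in 12 and lower in 1 of 16, both alike adjusted over the list alone. Neural plate border genes were higher in 13 and lower in 1 of 19 (14 and 1 adjusted over the list alone), and neural crest specifiers higher in 13 and lower in 4 of 23 (13 and 4 adjusted over the list alone). SOX10 rose from 1.82 to 6.33 (log2 1.796 ± 0.46), while MYC fell from 39.9 to 5.43. Midbrain and hindbrain genes were higher in 10 and lower in 2 of 12 (10 and 2 adjusted over the list alone). FGF pathway genes were higher in 2 and lower in 7 of 12 (2 and 7 adjusted over the list alone), Notch pathway genes higher in 6 and lower in 3 of 15 (7 and 3 adjusted over the list alone). Neural progenitor genes were higher in 8 and lower in 1 of 15 (9 and 1 adjusted over the list alone) and neurogenesis genes higher in 9 and lower in 3 of 24 (10 and 3 adjusted over the list alone). Neural crest derivative genes were higher in 7 and lower in 3 of 19 (8 and 4 adjusted over the list alone). Anterior neural genes were higher in 4 and lower in 3 of 11 (5 and 3 adjusted over the list alone), with OTX1 going from 1.25 to 39.0 and HESX1 and FEZF1 falling from 25.4 to 1.34 and from 21.2 to 1.00. Genes of nonneural ectoderm and placodes were higher in 5 and lower in 2 of 14 (8 and 3 adjusted over the list alone), EYA4 going from 0.0338 to 2.82 and GRHL2 falling from 6.41 to 0.0610. Of 39 HOX genes only 3 were tested, and all 3 were higher (3 and 0 adjusted over the list alone). Among these were HOXB1 and HOXB2, listed at 0 on day 0 and at 1.04 and 0.687 on day 5.

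Adhesion and EMT genes were higher in 10 and lower in 7 of 22 (10 and 7 adjusted over the list alone). CDH2 rose from 15.8 to 157 and VIM from 317 to 960.1. The list's median was 0.46 and its mean -0.18. Proliferation genes were lower in 3 of 20 (3 adjusted over the list alone), namely MCM3 (144 to 81.2), MCM5 (95.9 to 42.0) and CCNE1 (19.8 to 9.27), and none was higher. MKI67 stood at 16.4 on day 0 and 25.6 on day 5 without a call. Cell cycle inhibitors and p53 targets were higher in 4 and lower in 2 of 14 (4 and 2 adjusted over the list alone), GADD45A rising from 18.7 to 65.1. Stress genes were lower in 7 of 18 and higher in 0 (7 and 0 adjusted over the list alone), and chromatin genes higher in 3 and lower in 3 of 14 (5 and 3 adjusted over the list alone). Glycolysis genes were lower in 5 of 18 and cholesterol synthesis genes lower in 5 of 17, none was higher, and both counts were 5 adjusted over the list alone. HK1 fell from 89.8 to 21.5 and SLC2A1 from 147 to 78.7, and the sterol reductase DHCR7 fell from 78.7 to 38.6. Of 15 housekeeping genes only HPRT1 was called, falling from 41.9 to 24.4 (0 adjusted over the list alone).

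Lists of markers of other cell types that the culture could hold were also counted. Of the mesendoderm list 3 were higher and 3 lower on day 5 than on day 0 of 13 tested (6 and 4 adjusted over the list alone). FOXA1, FOXC1 and MEOX1 were higher at day 5 values of 0.761, 0.429 and 0.920, and TBX6 fell from 3.81 to 1.11. Of 6 tested endothelial genes 3 fell and none rose (3 and 1 adjusted over the list alone), KDR from 22.2 to 2.65 and FLT1 from 25.6 to 0.178. Of 6 tested muscle genes 1 fell (3 lower and 1 higher adjusted over the list alone), MYL7 from 3.14 to 0.229. Hepatic and gut endoderm genes counted 1 higher and 1 lower of 5 (1 and 1 adjusted over the list alone), with VIL1 falling from 4.51 to 0.0787. Trophoblast and amnion genes counted 1 higher and 3 lower of 5 (1 and 3 adjusted over the list alone), with TFAP2C rising from 2.57 to 7.68 and KRT7 falling from 8.45 to 0.336. TFAP2C is also on the nonneural ectoderm and placode list, so its rise is not particular to trophoblast and amnion.

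The FOX family of 49 measured genes, to which FOXB1 belongs, moved in different directions. By day 3, 4 were higher and 10 lower of 26 tested (4 and 11 adjusted over the list alone). FOXO1 fell from 14.9 to 1.78 and FOXO4 from 10.5 to 3.16. In the step to day 5, 4 were higher and 3 lower of 28 (4 and 3 adjusted over the list alone). By day 5, 6 were higher and 8 lower than on day 0 of 31 tested (8 and 8 adjusted over the list alone). FOXH1 ended at 1.21 and FOXA3 at 3.72. At a q below 0.05, FOXB1 was the only family member that rose and then fell, and FOXD3 the only one that fell and then rose.

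From day 0 to day 5, 2007 genes were higher and 2417 lower of 16409 tested, at a q below 0.05 in the authors' deposited table. The median log2 ratio of all genes at an FPKM of at least 1 in both groups was -0.01. The normal p of the test statistic gave 1238 higher genes.

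Cross-classifying the steps separated genes that moved steadily from those that turned on day 3. Among 15564 genes tested in both steps, 206 rose in both, among them WNT1, PAX3, MSX1, NR2F1 and NR2F2, and 260 fell in both, among them POU5F1, ESRG, ZSCAN10 and GAL. Another 276 rose and then fell, and 193 of these were not called between day 0 and day 5. VGLL3, DBX1, FOXB1, NTRK2, CYP26C1 and SOX21 led this class when genes were ranked by their smaller step. The reverse course was taken by 175 genes, of which 121 were not called between day 0 and day 5. ID1 (119, 11.3 and 174), FOXD3, EGR1, FOS and ETS1 (7.27, 1.11 and 6.14) led it. Genes called in the first step without a call in the second numbered 972 higher and 1449 lower, of which 972 and 1135 were tested in both steps. Those called in the second without a call in the first numbered 564 higher and 528 lower, of which 451 and 528 were tested in both.

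Lists of that length drawn independently would share 77.7 genes that rose in both, 107 that fell in both, 99.4 that rose then fell and 83.9 that fell then rose. The steps share the day 3 libraries, which favours opposite calls. With no effect at all, 100 simulations on the implied standard errors of 15330 genes, called at a statistic of 1.90, gave 176 opposite and 0.5 same-direction calls on average, with at most 206 and 5. At that same statistic these genes had 525 opposite and 562 same-direction calls, against 425 and 459 by the q in the authors' deposited table. Part of the excess of opposite calls may come from the shared libraries, which could not be divided. At a q threshold of 0.01, 121 genes rose in both steps, 129 fell in both, 164 rose then fell and 84 fell then rose. Under the normal p, 103 rose in both, 166 fell in both and 83 fell then rose.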

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

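Each value here comes from a gene that no comparison tested, at an FPKM of at least 300 on a later day and at least 1.5 times its day 0 value, a criterion chosen after seeing the data. The pseudogene H3F3AP4 stood at 917 on day 0, 1631 on day 3 and 1457 on day 5. Its parent gene H3F3A, which was tested, was listed at 688, 2.86 and 3.09 without a call. For H3F3A the change to day 3 was log2 -7.91 ± 8.54, at a locus shared with another gene, so no fall can be read from it. MIR3198-2 was at 416, 1700.1 and 1437, and MIR4683 at 69.4, 408 and 90.2. MIR1827, MIR3679 and SNORD34 were listed at 0 until day 3 and at 349, 303 and 528 on day 5. MIR4449 was at 378 on day 3 and listed at 0 on the other days. Between day 0 and day 3 the test status was NOTEST for MIR1827, MIR3679, MIR4449 and SNORD34, and LOWDATA for H3F3AP4, MIR3198-2 and MIR4683. FPKM divides by length, so a high value of a very short gene can rest on few fragments, and the number of fragments is unknown. These genes are not part of the counts above. No explanation was tested for them.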

How the results depend on the processing

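The normal p of the deposited test statistic and the removal of small RNA genes or of genes sharing a locus were chosen after seeing the data. No paired analysis was possible because the table gives 1 value per group and no value per replicate, and leaving out a replicate in turn was not run for the same reason. Among alternative counts of genes or lists, 100 lay within 1.5 times the main count and 17 did not, all 17 of them under the stricter q threshold or the normal p. At a q of 0.01, 946 genes were higher on day 3 than on day 0, 586 higher and 619 lower on day 5 than on day 3, 121 rose in both steps, 129 fell in both, 164 rose then fell, 84 fell then rose and 326 fell in the second step with no call in the first. Under the normal p, 915 genes were higher on day 3 than on day 0, 530 higher on day 5 than on day 3 and 1238 higher on day 5 than on day 0. It left 103 that rose in both steps, 166 that fell in both, 83 that fell then rose, 615 that rose in the first step with no call in the second, and 344 that rose and 349 that fell in the second with no call in the first. A stricter threshold calls fewer genes by construction, and for the normal p the cause was not tested further than the comparison of statistic and p given in the methods. Of the 4424 genes called between day 0 and day 5, the normal p kept 2842 and added 264. Each of the genes with the largest changes, and FOXB1 where called, kept its call under the normal p except SNAR-C3, which has no statistic because day 3 is listed at 0. For named genes a pseudocount of 0.1 or none cannot change the direction of a fold, so these alternatives say nothing about it. For the gene lists, 370 alternative values stayed on their side of the central 95% of random lists, 31 moved outside it and 24 inside, and 6 values of lists that had lain outside it changed sign. Another 20 values of lists inside that range, 13 of them means, had the opposite sign to the main median. The median reversed for the nonneural ectoderm and placode list between day 0 and day 3 (-0.14 with members at an FPKM of at least 1, and a mean of -0.038) and for the neurogenesis list between day 3 and day 5 (-0.48 and a mean of -0.13). The mean had the opposite sign to the median for adhesion and EMT genes between day 0 and day 5 (-0.18) and for stress genes between day 3 and day 5 (0.0578). The cause of these changes of sign was not tested. Depth per library is unknown, so no detection limit can be given for genes listed at 0.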

Other observations

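The tests below on genes that turned on day 3 were chosen after the result was seen, as were the values without small RNA genes and the look at small errors, and the other tests on uncalled genes and on genes listed at 0 before it. Gene families in the next sentences were also taken by symbol after the values were seen. Of 9 tested metallothioneins, small metal-binding proteins, 7 fell between day 0 and day 3 and none rose. Besides MT1G and MT1H, MT1X went from 327 to 32.1 and 14.0 over the 3 days, MT2A from 192 to 19.7 and 14.8, MT1E from 110 to 11.1 and 5.97, MT1F from 56.8 to 10.6 and 3.52, and MT1M from 10.2 to 0.646 and 0.552. Ephrins and Eph receptors, which guide cell sorting and migration, were higher in 9 and lower in 3 of 21 tested by day 3, and higher in 3 and lower in 5 of 20 in the next step. EFNB1 rose from 2.96 to 59.4 (log2 4.33 ± 0.36) and fell to 34.0, EPHB3 rose from 0.576 to 5.41 and fell to 2.34, and EPHA4 rose from 4.66 to 23.9. EPHA7 rose in both steps, from 2.03 to 4.68 and 33.3. Of the IRX family, IRX1, IRX2, IRX3 and IRX5 rose by day 3 and IRX4 fell, from 0.863 to 0.0988.

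Of 17 measured genes of retinoic acid handling, 16 of them tested in each step, 5 had opposite calls in the steps, as did 451 of all 15564 genes tested in both. Retinoic acid handling is 1 of 18 families looked at, in which that number ranged from 0 of 77 measured ribosomal protein genes to 8 of 47 measured collagens. As a share of measured genes it was higher in the small IRX (3 of 6) and ID (2 of 4) families. Enrichment was not tested. RARB, a retinoic acid receptor that retinoic acid itself induces, rose from 0.148 to 10.5 and fell to 1.02, and CYP26A1 went from 20.8 to 59.9 and 3.65. ALDH1A1 and ALDH1A3, which make retinoic acid, went the other way, from 0.549 to 0.134 and 5.25 and from 1.67 to 0.399 and 3.19, each called in both steps. Others did not turn: DHRS3 fell from 18.4 to 2.04 with no call in the next step, and the binding protein CRABP1, not called in the first step, rose from 281 on day 3 to 877 on day 5.

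FOXB1 and others rose to day 3 and fell again, or the reverse. At a statistic of 1.90, 525 genes had opposite calls, and 425 by the deposited q. Simulations without effect gave at most 206 at that statistic, so error of the implied size in unchanged genes would not give the whole count. The simulations held no changed genes and took the implied errors as normal. Those errors may leave out spread between cultures and do not always match the deposited q. The simulations therefore cannot bound how much of the class is error in the shared day 3 value. A single wrong scaling factor on day 3 would not account for most opposite calls, since the factor that left the fewest, at the same statistic, still left 508. That factor shifted the balance, from 316 that rose then fell and 209 the reverse to 251 and 257. A candidate explanation is that a neural progenitor programme passes through a high on day 3 together with FOXB1. In the class that rose then fell were 4 of 15 members of that list (26.7%) against 271 of 15548 other genes without FOXB1 (1.74%), with a one-sided Fisher's exact p of 0.000112, though genes are not independent replicates. The test cannot tell a later fall from the rise alone, since 10 of the 15 members rose by day 3. Of these 10, 4 then fell, against 276 of all 1454 genes that rose by day 3. The share above that of other tested genes was not particular to that list, as of 30 lists 3 had an adjusted p below 0.05, the others being neural plate border genes (5 of 18, adjusted p 0.000354) and neurogenesis genes (4 of 20, adjusted p 0.0037) beside 0.00167 for neural progenitors. The same limit holds for these, as 15 of the 18 and 8 of the 20 rose by day 3. Which programme FOXB1 goes with, and whether it drives or follows it, stays open.

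A second pattern is a set of 72 genes that changed at least 4-fold at an FPKM of at least 5 and were called in no comparison in which they changed that much. Examples are MAB21L2 (0.202, 8.67 and 83.0), EPHA1 (42.4, 2.15 and 0.396), CLDN7 and SAMD11 (0.341, 0.488 and 21.1). Few reads stay open as a cause: the median FPKM in the higher group was 21.9 against 15.2 in called genes of that size, but FPKM divides by length, the median reference length was 133 against 28495 bases, and without the 41 small RNA genes the FPKM medians were 15.1 and 15.2. Reads shared between overlapping gene models may have widened the error of part of the set, as a locus shared with another gene was found for 60 of the 72 (83.3%) and for 143 of 919 called genes (15.6%), with a one-sided Fisher's exact p of 3.82e-33, and without small RNA genes for 28 of 31 and 142 of 918. This leaves out 15 genes, 14 small RNA genes and SNAR-C4, of which 5 share a locus. Their implied standard error was below the median of 0.476 in called genes. Nor does a wide error alone account for every other gene. Between day 0 and day 3 some changed by several times their implied error. GDF3 (log2 -8.04 ± 1.39, q 0.282) and PF4 (-7.87 ± 1.63, q 0.495) were alone at their locus. CLDN7 (-5.72 ± 1.62) and EPHA1 (-4.30 ± 1.13) shared theirs. Others, such as H3F3A (-7.91 ± 8.54), had an error above their change. Genes of either kind were not counted. Disagreement between the replicates stays open too, as no value per library was used.

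In the last pattern, 80 genes were called against a group listed at 0. Very short genes, whose FPKM swings with few reads, could account for part of them, as 19 were small RNA genes and 20 of the 74 with a reference length were under 300 bases. The median length was 3081 bases against 35733 in other called genes. These lengths include introns, so they cannot show how many of the transcripts are short, and short genes as the whole cause stay open. No biological explanation was tested for this or for the uncalled genes.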
